A study of Arabidopsis thaliana with 12 samples.

How the data were processed

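The series compares whole seedlings of Arabidopsis thaliana, the wild type Columbia (Col) and the CCA1 overexpressor CCA1-34, at 2 times of day, with 3 arrays in each of 4 groups. Per the labels' protocols, about 100 seedlings were grown per dish on medium with sucrose, collected in darkness with infrared goggles and frozen at once, and biotin-labelled cRNA was made from 5 ug of total RNA for Affymetrix arrays. The values are on the log2 scale, and the authors made them with RMA, per the file headers and the submitters' processing notes. The version, settings and chip description are not given in the sources used here. RMA usually includes background correction, quantile normalization across arrays and summary of probes to probe sets, which makes the arrays' distributions nearly equal, so that a shift of most transcripts in 1 direction would be reduced. The values range from 1.22 to 12.99, with array medians of 4.01 to 4.12 and interquartile ranges of 3.61 to 3.69. The table of the whole series held the same values as the per-array files in every cell (0 differed), and all of its columns were matched to samples.

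Groups and replicate numbers came from the sample titles, and ages and times from the descriptions. Of 22810 probe sets, 64 array controls were left out, and 22746 were tested. The files pair 21361 of these with 1 locus, 885 with several and 500 with none, and genes were named from probe sets with 1 locus alone. Symbols came from a table of NCBI's TAIR10.1 annotation, in which 21048 of the single-locus probe sets (98.5%) had their locus and 9060 a symbol. No coordinates are given, because no genome build is named for the array files.

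Differences between groups were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes without trend, two-sided) on the deposited values of all 12 arrays with 4 group means, so that the groups share 1 estimate of the spread. No filter on dim probe sets was used. P-values were adjusted by Benjamini-Hochberg over the 22746 probe sets at a threshold of 0.05. The fit had 8 residual degrees of freedom (the written design had stated another number by mistake), a median residual SD of 0.201 and a median standard error of 0.160 for a difference of 2 groups. The 5 contrasts were Col early minus late, CCA1-34 early minus late, the difference of these as the interaction, and CCA1-34 minus Col at each time. Growth-associated probe sets had to pass against Col late in each of the 3 growing groups with the same sign. Seedling age was fitted as a slope over 5, 6 and 7 days with the group as a factor. For single genes, exact permutation tests of the array values were run. The labels do not say whether arrays of different groups and days came from independently sown cultures, so p-values measure the spread between these samples.

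Gene lists were fixed before the data were examined, as were the contrasts, the test, the other settings to be tried and the rule for naming genes. There were 19 lists: morning-phased clock (10 measured genes), evening-phased clock (10), PIF and growth-related bHLH factors (16), shade- and PIF-induced genes (15), auxin-induced genes (20), cell wall loosening and cellulose (31), gibberellin (18), brassinosteroid (10), abscisic acid and cold or dehydration response (20), ethylene (11), light harvesting and chlorophyll (15), photoreceptors, light and photoperiod regulators (23), flavonoid synthesis (12), dark- and sugar-starvation-induced genes (8), starch (13), cell cycle (8), and, as controls, handling, touch and heat response (12), root cell markers (13) and seed and embryo markers (9). Each gene was represented by its probe set with the highest mean. Some lists share genes, such as HFR1 in the bHLH and shade lists and IAA29 in the shade and auxin lists. Their results are therefore not independent, and a shared gene counts in each of its lists. Lists were tested with limma's camera at its preset correlation of 0.01, adjusted over the 95 tests of 19 lists in 5 contrasts. Camera with an estimated correlation and fry, whose p tests whether a list moves on balance one way and whose mixed p tests for change in either direction, were alternatives. In 11 of the 95 tests the median, the mean and the test differed in sign, and 0 of these passed. Members were also adjusted over the list alone with limma's p-values, and "rose" and "fell" are used of members on that basis where it is stated.

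The rule for named genes took, per contrast, the 8 largest rises and falls past the threshold among probe sets with 1 gene whose groups' arrays did not overlap, up to 3 members per list past the threshold (4 for the clock and bHLH lists), and always CCA1, LHY, TOC1, PIF4 and PIF5. For growth it took 8 per direction by the smallest of the 3 differences, of which those that missed an unadjusted p of 0.05 in any of the 3 contrasts are not named, and for age the 5 steepest slopes per direction. Since 0 members passed over all probe sets in the 5 contrasts, members were named by the adjustment over the list alone, which was decided after their values were seen. List tests of the age slope and the permutation tests were also added then. Second lists of 8 light-induced and 11 dark-induced genes were written after arrays had been seen to stand apart and before the lists were tested.

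The replicate number marks the day of sampling in the labels and so pairs samples across groups. Deviations from the group means correlated with a mean r of 0.161 in the 18 pairs of arrays of the same day (-0.317 to 0.505, with 12 over 0.1) and of -0.0808 in the 36 pairs of different days. The fit with the day as a block was an alternative, and its value stands beside a result where it changed the call or moved a count by more than 1.5 times. Other alternatives were an intensity trend with a robust prior, median centring, quantile normalization, leaving out probe sets whose highest group mean was below 6, a minimum log2 change of 1 (0.5 per day for age), array weights, a fit on the 2 compared groups alone, and leaving out each array or the 4 arrays of each age in turn. Leaving out both Col early replicate 3 and CCA1-34 early replicate 2 was added after the data were examined.

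The scripts' tests were tested on simulated data. For Col early minus late with 200 of 22746 probe sets changed, 62% of the 50 changed by 1, 80% of those changed by 2, 100% of those changed by 3 and 96% of those changed by 4 were recovered, with 6 false calls. For the age slope 98% at a slope of 1 per day and 100% at 2, 3 and 4 were recovered, with 14 false calls. A shift of 0.5 put into the auxin list was recovered, with 0 false calls among 92 other list tests. The simulated noise was independent between probe sets, had the same spread in every group and held no effect of the day. The dimmest probe sets were not among those changed. These counts of false calls thus do not cover lists whose genes vary together. Likewise the recovered shares do not cover the dimmest probe sets, unequal spreads or a day effect. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.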

Results

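Transcript levels were measured in whole Arabidopsis thaliana seedlings on 12 Affymetrix arrays, 1 per sample, each with 22746 probe sets besides array controls. The wild type Columbia (Col) was set against CCA1-34, a line without circadian rhythm that overexpresses CCA1, a Myb-related transcription factor of the plant clock. After 4 short days of 8 h light and 16 h dark, the seedlings received light pulses of 160 min separated by 320 min of darkness. The labels give 3 days for this regime. The seedlings were harvested 120 min after lights-off, at 280 min after dawn (early) or at 1240 min (late). Per the series' design text, darkness was accompanied by growth of Col at the early time but not at the late time, and by growth of CCA1-34 at both. Each of the 4 groups held 3 arrays, replicates 1, 2 and 3, from seedlings aged 5, 6 and 7 days, so that n = 3 for every group mean. All values were the deposited log2 values, and all differences are on the log2 scale. Array medians lay between 4.01 and 4.12, and arrays of the same group correlated across probe sets with r between 0.962 and 0.992. The number of arrays limits the precision.

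Genes regulated by light and darkness set 1 array of each early group apart from its group. In Col early replicate 3, 18 of the 23 measured photoreceptors, light and photoperiod regulators were higher than in the mean of the group's other arrays, by 1.01 on average. In CCA1-34 early replicate 2, 18 of the 23 were higher, by 1.31 on average. The 8 genes induced by darkness and sugar starvation averaged -1.31 and -1.54 against the other arrays of the respective group. IAA29, an auxin-response repressor gene picked as an example after its values were seen, stood at 3.42 in Col early replicate 3 against 6.92 and 7.62, and at 4.24 in CCA1-34 early replicate 2 against 6.38 and 8.05. Genes of handling, touch and heat response were higher in Col early replicate 3, by 1.08 on average over 12 genes with 11 of them higher, while their mean difference in CCA1-34 early replicate 2 was 0.05. A smaller difference of the same kind was present in Col late replicate 1, with 0.30 for the light regulators and -0.97 for the starvation genes. Root cell markers, a control for the share of root tissue, set arrays of all 4 groups apart from the others of their group. All 13 were higher in Col late replicate 2, by 0.90 on average, and 0 of 13 in Col late replicate 3, with -0.85, where the starvation genes were 1.12 higher. In CCA1-34 late 11 of 13 were higher in replicate 1 (0.69) and 2 of 13 in replicate 3 (-0.60), and in CCA1-34 early 11 of 13 in replicate 1 (0.58) and 1 of 13 in replicate 3 (-0.39). In Col early 10 of 13 were higher in replicate 1 (0.30) and 3 of 13 in replicate 3 (-0.36). All 12 arrays were kept in the comparisons, and counts without both early arrays are given as an alternative chosen after the data were examined.

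**Figure D1:**
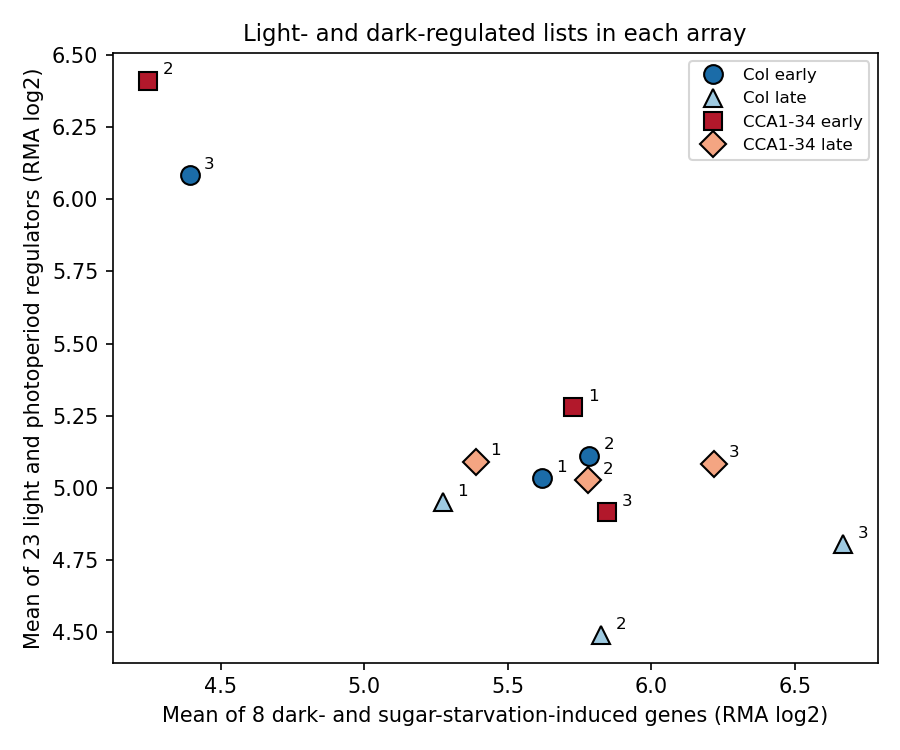
Each point is 1 array, numbered by replicate: the x axis is the mean RMA log2 value of the 8 genes induced by darkness and sugar starvation, and the y axis that of the 23 photoreceptors, light and photoperiod regulators, with colours for the 4 groups. Col early replicate 3 (4.39 and 6.08) and CCA1-34 early replicate 2 (4.25 and 6.41) lie at the upper left of the other 10 arrays.

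The CCA1 transcript was higher in every CCA1-34 array than in any Col array, with 8.46 to 10.2 in CCA1-34 and 2.47 to 6.37 in Col. Group means were 4.35 ± 1.95 in Col early, 3.27 ± 0.54 in Col late, 8.91 ± 0.39 in CCA1-34 early and 9.39 ± 0.69 in CCA1-34 late (SD, n = 3). Over all arrays of each line the difference was 5.34 (exact permutation test, two-sided, p = 0.00216, the smallest that the 924 assignments of 6 against 6 arrays allow). In limma's fit over all probe sets the difference was 4.56 at the early time (SE 0.777, adjusted p = 0.627) and 6.12 at the late time (adjusted p = 0.0588, or 0.0360 with the day of sampling as a block). The Col late values, 2.66 to 3.71, lay below the array medians and were not shown to be above background, so the late difference is at best a lower bound. Without Col early replicate 3, the array with the highest CCA1 value of Col, the early difference was 5.57 (adjusted p = 0.0185). The late difference passed without Col early replicate 1 (adjusted p = 0.00840) or without Col early replicate 3 (0.00285). LHY, the close partner of CCA1 in the clock, differed by -0.99 early and -1.90 late, and TOC1, an evening clock gene, by -0.56 and -0.42, and neither passed. With the day as a block TOC1 passed over the evening-phased list alone at both times (adjusted p 0.0291 and 0.0497).

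ACBP6, which encodes a cytosolic acyl-CoA-binding protein, did not overlap between the lines either. It lay between 3.44 and 3.85 in the 6 Col arrays and between 10.7 and 11.2 in the 6 CCA1-34 arrays. The difference was 7.25 early (SE 0.117, limma adjusted p = 1.79e-10) and 7.38 late (adjusted p = 1.49e-10). The call held in both comparisons without any 1 array. The Col values lay below the array medians and were not shown to be above background, so the difference is at best a lower bound.

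**Figure D2:**
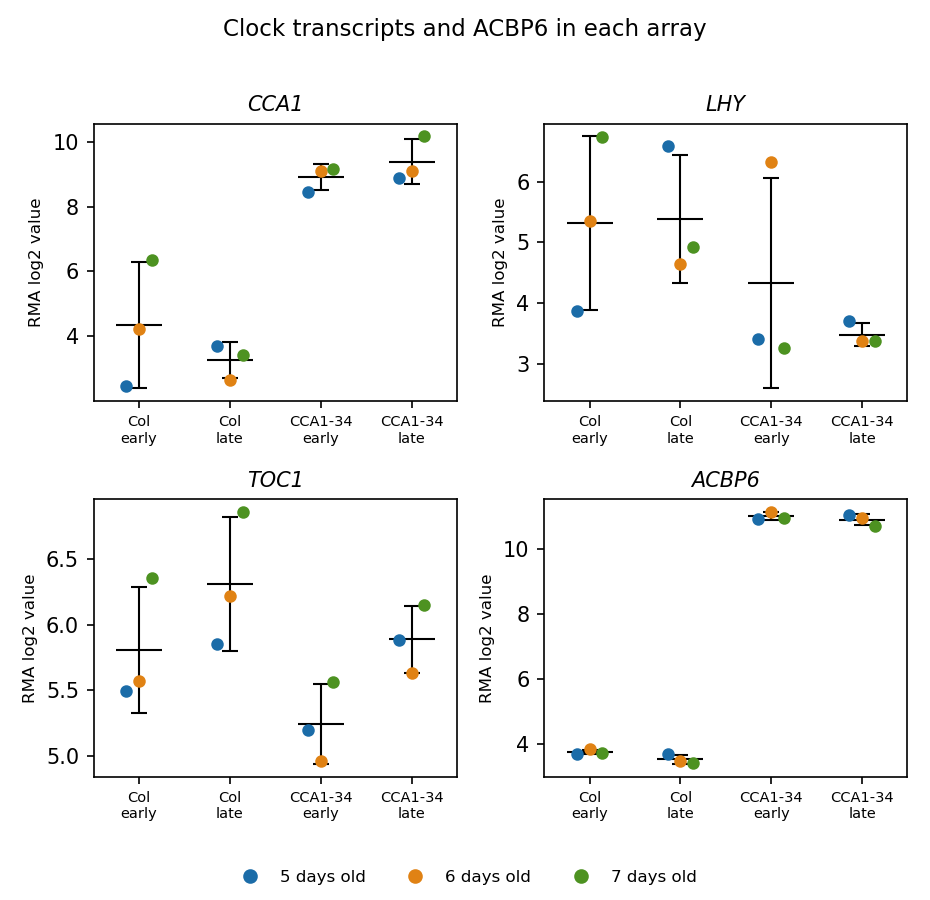
RMA log2 values of CCA1, LHY, TOC1 and ACBP6 in the 4 groups: points are arrays, coloured by seedling age of 5, 6 or 7 days, horizontal bars are group means and whiskers are SDs (n = 3). ACBP6 lies between 3.44 and 3.85 in Col and between 10.7 and 11.2 in CCA1-34, and CCA1 is higher in every CCA1-34 array than in any Col array.

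Col at the early time, when seedlings grew, was compared with Col at the late time, when they did not. Within Col, growth and time of day cannot be told apart. PIF4 and PIF5, bHLH factors that promote elongation in darkness, rose together: PIF4 was 6.43 ± 0.14 early and 3.90 ± 1.19 late (SD, n = 3), a difference of 2.52 (SE 0.463), and PIF5 was 2.53 higher (SE 0.494). Adjusted over the list alone these were the calls among 16 PIF and growth-related bHLH factors, both with limma adjusted p = 0.00308 (0.348 and 0.382 over all probe sets). Clock genes moved as well. Of 10 morning-phased clock genes 5 rose and 1 fell, adjusted over the list alone, among them LNK4 (2.53), LNK1 (2.43) and LNK3 (2.25), members of a family of clock coactivators, and RVE2 (-3.15, SE 0.644), a Myb factor related to CCA1. Among 10 evening-phased genes GI rose by 3.00 (SE 0.626, adjusted p over the list alone = 0.00630). CCA1, LHY and TOC1 differed by 1.08, -0.06 and -0.50 and did not pass.

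Auxin-induced genes were higher in 18 of 20 cases, and 3 rose, adjusted over the list alone: GH3.3 (2.17) and GH3.5 (1.58, SE 0.277), which conjugate auxin to amino acids, and the small auxin-up gene SAUR9 (1.59). All 15 shade- and PIF-induced genes were higher, with a median of 0.72, although no single member passed. These counts compare group means, and Col early replicate 3 did not share the rise. Its mean over the shade list was 4.196, below Col late replicates 2 (4.401) and 3 (4.546). Its auxin mean (5.203) and bHLH mean (4.643) lay below those of Col late replicate 3 (5.329 and 5.134). Col early replicates 1 and 2 lay above every Col late array in each of these lists. Of 23 photoreceptors, light and photoperiod regulators 4 rose, adjusted over the list alone: the cycling Dof factor CDF3 (2.98, SE 0.50), the B-box factors BBX24 (2.69) and BBX22 (0.82), and the photoreceptor gene PHYB (0.58). GA20OX1, a gibberellin biosynthesis gene, rose by 1.54 and ISA3, a starch debranching enzyme, by 0.78, again over their lists alone. Over all probe sets none of these members passed. With the day as a block GA3OX1 (1.27, adjusted p over the list alone 0.0212), DPE1 (0.73, 0.0377) and DPE2 (0.42, 0.0382) passed as well, of gibberellin synthesis and of starch breakdown.

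As lists, 8 of the 19 were higher at the early time by camera with its preset correlation, and none was lower. The median differences and adjusted p-values were 1.26 and 0.00885 for the morning-phased clock, 0.53 and 0.00113 for the bHLH factors, 0.72 and 6.18e-06 for the shade- and PIF-induced genes, and 0.55 and 1.62e-06 for the auxin-induced genes. They were 0.53 and 0.00113 for the photoreceptors and light regulators, 0.26 and 0.000798 for abscisic acid and cold response, 0.19 and 0.0005 for starch genes, and 0.36 and 0.00885 for handling, touch and heat response. None held with an estimated correlation, where the lowest adjusted p was 0.384 with an estimated correlation. The lists for cell wall loosening (median 0.06, adjusted p = 0.198), gibberellin (0.13, 0.208), brassinosteroid (-0.11, 0.443), ethylene (0.30, 0.122), light harvesting and chlorophyll (0.10, 0.247), flavonoid synthesis (0.05, 0.639), dark- and sugar-starvation-induced genes (-0.25, 0.25), cell cycle (-0.06, 0.783), root cell markers (0.11, 0.449) and seed and embryo markers (-0.40, 0.517) did not pass. For the evening-phased clock genes the median was -0.24 and the mean 0.13, and the test, in the downward direction, gave adjusted p = 0.672.

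Over all probe sets 1 of 22746 passed in limma, with 1230 at an unadjusted p under 0.05 against 1137.3 by chance. It was AT1G73480, a predicted alpha/beta hydrolase gene, at 6.16 ± 0.15 early and 3.5 ± 0.11 late (SD, n = 3; difference 2.66, SE 0.271, adjusted p = 0.0293), and its call was lost without any 1 of the 6 Col arrays or without CCA1-34 late replicate 1 (adjusted p between 0.0820 and 0.263). The count was 0 without Col early replicate 1 or 3, Col late replicate 1 or 2, or CCA1-34 late replicate 1, 2 without Col late replicate 3 and 3 without CCA1-34 early replicate 2. The groups' arrays did not overlap for 8.91% of probe sets, where chance gives 10%. The list calls rested in part on single arrays. Without Col early replicate 3 the medians and adjusted p-values were 0.80 and 0.239 for the morning-phased clock, 0.14 and 0.168 for the light regulators, 0.16 and 0.157 for starch and 0.06 and 0.576 for handling response, while the medians of the auxin-induced genes (0.89) and the bHLH factors (0.86) were larger. Without Col late replicate 2 the first 4 gave adjusted p-values of 0.143, 0.139, 0.0917 and 0.0677. Without Col early replicate 2 the bHLH list gave 0.31 (0.0571) and starch 0.51, without Col late replicate 3 starch gave 0.40, and without Col late replicate 1 abscisic acid and cold response gave 0.39. Of the 18 member calls 11 held without any 1 array, and 7, those of LNK1, LNK2, GH3.3, SAUR9, GA20OX1, BBX22 and ISA3, were lost without Col late replicate 1 (adjusted p over the list alone 0.0614 to 0.144) and some also without other Col or CCA1-34 late arrays (up to 0.177).

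**Figure D3:**
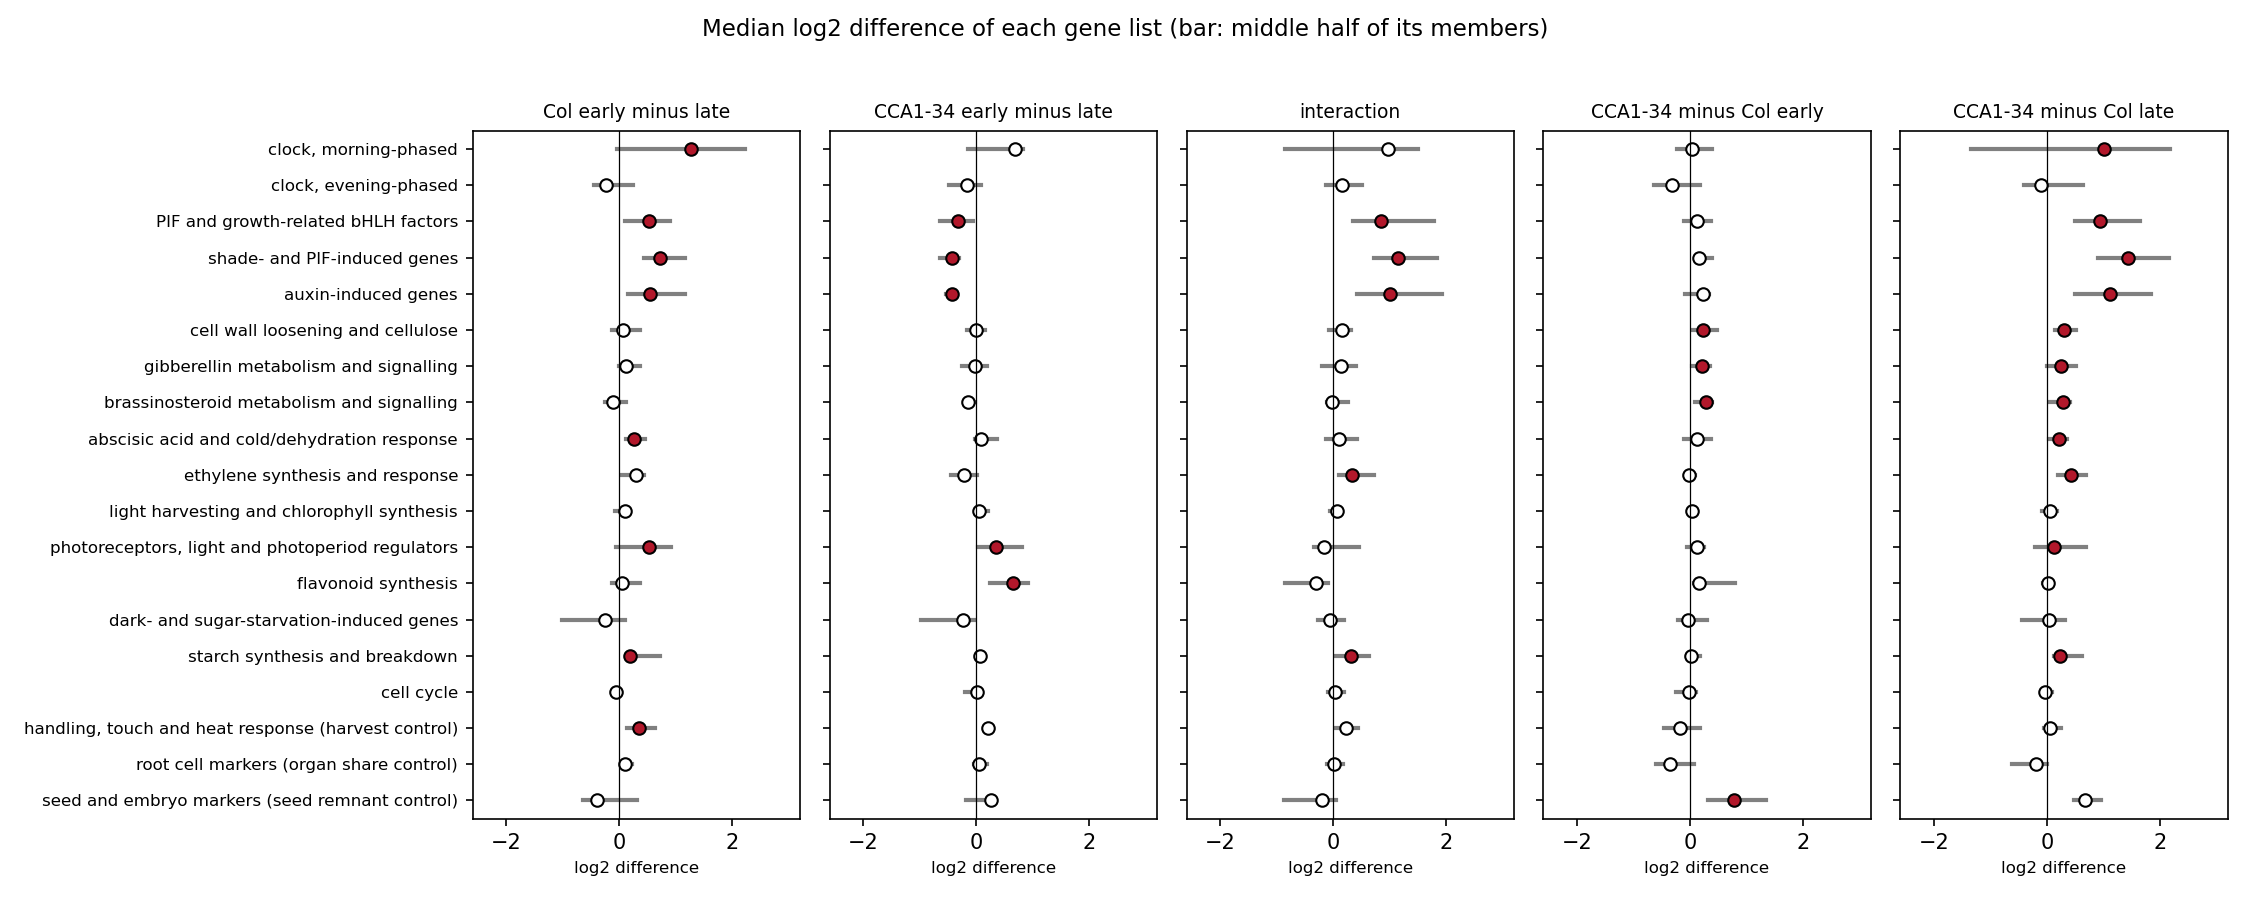
Each panel is 1 comparison and each line of it 1 of the 19 gene lists: points are the median log2 difference of the list's measured genes, grey bars span the middle 50% of its genes, and filled red points mark lists with a camera adjusted p under 0.05 at the preset correlation. The shade- and PIF-induced genes and the auxin-induced genes have medians of 0.72 and 0.55 for Col early minus late, -0.42 and -0.44 for CCA1-34 early minus late, and 1.44 and 1.11 for CCA1-34 minus Col late.

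In CCA1-34, which grew at both times, 3 lists, of auxin, shade and bHLH genes, were lower at the early time than at the late time, while those for cell wall (median -0.01, adjusted p = 0.999), gibberellin (-0.02, 0.853) and brassinosteroid (-0.15, 0.139) did not pass. The 20 auxin-induced genes had a median difference of -0.44 (18 of 20 lower, camera adjusted p = 4.77e-06), the 15 shade- and PIF-induced genes of -0.42 (13 lower, 0.000272) and the 16 bHLH factors of -0.32 (13 lower, 0.00838). Flavonoid synthesis genes were higher, all 12 of them, with a median of 0.66 (adjusted p = 0.000890), as were the light regulators with 0.35 (0.00973). With an estimated correlation none of the 5 held, and the adjusted p for the auxin-induced genes was 0.393 with an estimated correlation. PIF4 differed by -0.06 (SE 0.463) and PIF5 by 0.13, and CCA1, LHY and TOC1 by -0.48, 0.85 and -0.64.

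No list member passed in CCA1-34 over time, adjusted over the list alone, although TOC1 did with the day as a block (-0.64, adjusted p 0.0266 against 0.524 without it). Over all probe sets limma passed 0 of 22746, and 0 with the block as well. At an unadjusted p under 0.05 there were 382, or 681 with the block, against 1137.3 by chance. Camera with the block also passed the evening-phased clock genes (median -0.17, adjusted p = 0.0330 against 0.160 without it). That is at the preset correlation, and without the block no list of this comparison passed at an estimated one (lowest camera adjusted p = 0.393). The list differences moved with CCA1-34 early replicate 2: without it the medians were -0.17 for the bHLH factors (adjusted p = 0.169), -0.14 for the shade- and PIF-induced genes (0.307), 0.32 for flavonoid synthesis (0.124) and -0.04 for the light regulators (0.747). The light regulators also missed the threshold without CCA1-34 late replicate 1 (0.23, 0.0804) or late replicate 2 (0.0688), and their median was 0.68 without early replicate 1 and 0.57 without early replicate 3. Flavonoid synthesis had a median of 0.36 without early replicate 1, 1.21 without early replicate 3 and 0.28 without late replicate 3, and the shade- and PIF-induced genes one of -0.73 without early replicate 3, while the auxin-induced genes passed without any 1 array. SESA5, a seed storage protein gene named after its values were seen, passed without CCA1-34 early replicate 3 (2.93, adjusted p = 0.0147), and 6.96% of probe sets did not overlap between the times, where chance gives 10%.

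The interaction asked directly whether the change from late to early differed between Col and CCA1-34. By camera at its preset correlation 5 lists had larger early-minus-late differences in Col than in CCA1-34, and none of them held with an estimated correlation. Auxin-induced genes had a median interaction of 1.01 (19 of 20 above 0, camera adjusted p = 1.07e-13), shade- and PIF-induced genes of 1.15 (15 of 15, 3.88e-11) and bHLH factors of 0.84 (14 of 16, 5.85e-07). Ethylene genes had a median of 0.33 (0.00885) and starch genes of 0.32 (0.00934), while cell wall (0.15, 0.247), gibberellin (0.14, 0.228) and brassinosteroid genes (-0.03, 0.754) did not pass. With an estimated correlation the 5 adjusted p-values lay between 0.127 and 0.562. SAUR9 (2.63, SE 0.544) and GH3.5 (2.0, SE 0.392) had larger early-minus-late differences in Col, both with adjusted p over the list alone of 0.00603, as had PIF4 (2.59, SE 0.655, 0.0395), PIF5 (2.40, 0.0477), GA20OX1 (2.14, 0.0386) and the auxin biosynthesis gene YUC8 (2.07, 0.0415). The SAUR9 means of Col early, Col late and CCA1-34 early lay below the array medians and were not shown to be above background. The size of its interaction is therefore uncertain, and the fit without dim probe sets did not test it. CCA1, LHY and TOC1 had interactions of 1.56, -0.91 and 0.14 that did not pass.

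Over all probe sets limma passed 0 for the interaction, with or without the block, and 465 had an unadjusted p under 0.05 against 1137.3 by chance. The calls of SAUR9 and GH3.5 held without any 1 array, and those of PIF4, PIF5, YUC8 and GA20OX1 were each lost without at least 8 of the 12 arrays (adjusted p over the list alone 0.0518 to 0.134); with the block YUC8 gave 0.0793 and GA20OX1 0.0943, while the light regulators CDF3 (2.54, 0.0304), BBX24 (2.26, 0.0304) and CDF5 (1.58, 0.0444) passed. The auxin, shade and bHLH lists passed without any 1 array, the last with a median of 0.51 without CCA1-34 early replicate 2. The ethylene list missed the threshold without Col early replicate 2 (0.177), Col late replicate 1 (0.0594) or CCA1-34 early replicate 2 (median 0.21, 0.213), and its median was 0.21 without CCA1-34 late replicate 3, 0.51 without late replicate 1 and 0.53 without Col late replicate 3. The starch list missed it without Col early replicate 3 (median 0.01, 0.530), Col late replicate 2 (0.11, 0.231) or CCA1-34 early replicate 3 (0.21, 0.0544), and had medians of 0.20 and 0.21 without CCA1-34 early and late replicate 2. With the block flavonoid synthesis passed too (median -0.30, adjusted p = 0.0476 against 0.0869 without it). That is at the preset correlation, and without the block no list of the interaction passed at an estimated one (lowest camera adjusted p = 0.127).

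**Figure D4:**
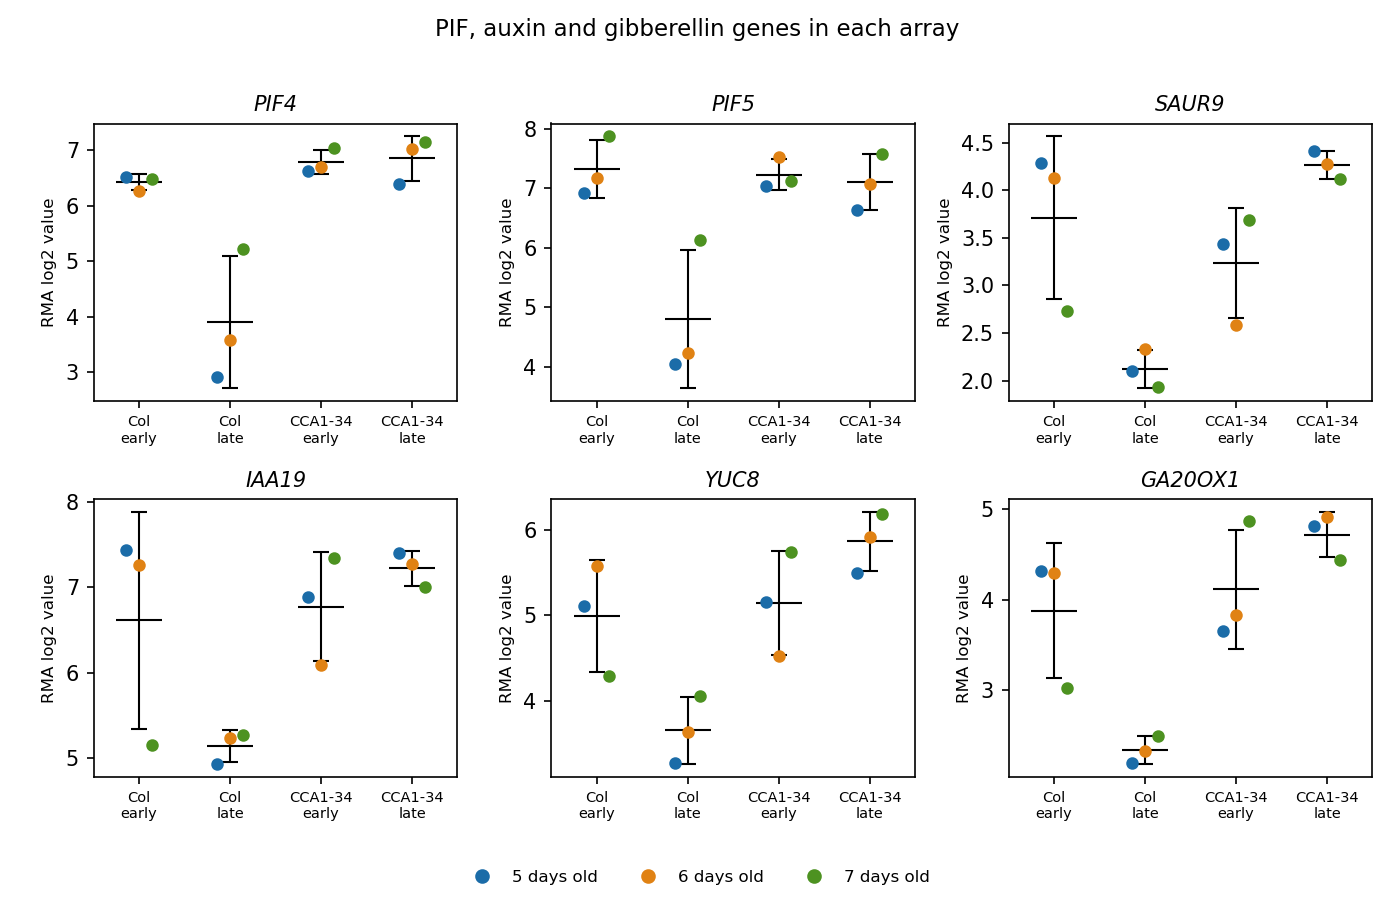
RMA log2 values of PIF4, PIF5, SAUR9, IAA19, YUC8 and GA20OX1 in the 4 groups: points are arrays, coloured by seedling age of 5, 6 or 7 days, horizontal bars are group means and whiskers are SDs (n = 3). Col late has the lowest mean of each gene, such as 2.12 for SAUR9 against 3.71 in Col early, 3.24 in CCA1-34 early and 4.27 in CCA1-34 late.

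The lines were next compared at the early time, when both grew. Besides ACBP6 and CCA1, 4 lists were higher in CCA1-34. The 31 cell wall loosening and cellulose genes had a median of 0.23 (26 of 31 higher, camera adjusted p = 0.000556), 18 gibberellin genes of 0.20 (0.00973) and 10 brassinosteroid genes of 0.29 (0.0124). Seed and embryo markers had a median of 0.78 (7 of 9 higher, 0.00403), and 2 of them, the late embryogenesis genes EM1 (1.76, SE 0.362, adjusted p over the list alone = 0.00527) and EM6 (1.43, 0.0456), rose. With an estimated correlation none of these 4 lists held, and the adjusted p of the cell wall list was 0.187 with an estimated correlation. IAA17, an auxin-response repressor, was 0.58 higher (0.0425 over the list alone). PIF4 differed by 0.37 and PIF5 by -0.10, and the bHLH, shade and auxin lists did not pass (medians 0.12, 0.16 and 0.23).

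ACBP6 was the 1 probe set that passed in limma, with 813 at an unadjusted p under 0.05 against 1137.3 by chance. Of all probe sets 7.76% did not overlap between the lines, where chance gives 10%. The count was 2 without Col early replicate 3 or CCA1-34 early replicate 2 and 3 without CCA1-34 early replicate 3. Without Col early replicate 3 the medians and adjusted p-values were 0.12 and 0.530 for the gibberellin list, 0.05 and 0.530 for the brassinosteroid list and 0.62 and 0.108 for the seed markers. Without CCA1-34 early replicate 3 they were 0.10 and 0.149 for the brassinosteroid list and 0.48 and 0.0682 for the seed markers, and without CCA1-34 early replicate 1 the gibberellin list gave 0.22 and 0.0846 and the seed markers a median of 1.35. Without Col early replicate 2 the medians were 0.50 for the brassinosteroid list and 1.67 for the seed markers. The cell wall list passed without any 1 array, with a median of 0.12 without Col early replicate 3, and gave 0.09 (adjusted p = 0.0583) without both early arrays that stand apart. The calls of CCA1 and EM1 over their lists held without any 1 array, while IAA17 was lost without 8 of the 12 arrays (up to 0.218, without CCA1-34 early replicate 2) and EM6 without 9 (up to 0.189, without Col early replicate 3). With the block PRR3 (0.91, adjusted p over the list alone 0.0291) passed too, and root cell markers did as a list, in the downward direction (median -0.36, adjusted p = 0.0378 against 0.114 without it). The list call is at the preset correlation, and without the block no list of this comparison passed at an estimated one (lowest camera adjusted p = 0.187).

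At the late time, when only CCA1-34 grew, growth-related genes were higher in CCA1-34. All 20 auxin-induced genes were higher, with a median of 1.11 (camera adjusted p = 3.99e-24), and 12 rose, adjusted over the list alone, among them IAA6 (2.29), SAUR9 (2.15, SE 0.385) and GH3.5 (1.76). All 15 shade- and PIF-induced genes were higher, with a median of 1.44 (8.14e-22), and 11 rose, among them IAA29 (3.25, SE 1.14), the sulfotransferase gene ST2A (2.93) and the bHLH factor HFR1 (2.66). Of the 16 bHLH factors (median 0.94, 1.73e-13) 7 rose: PRE1 (3.32, SE 0.602), PIF4 (2.95, SE 0.463, adjusted p over the list alone = 0.00103), HFR1, PIF5 (2.30, SE 0.494, 0.00314), BEE1, IBH1 and PIF6. None of the 3 lists held with an estimated correlation, where the adjusted p was 0.0973 for the auxin-induced genes and 0.127 for each of the others. The SAUR9 mean of Col late lay below the array medians and was not shown to be above background. GA20OX1 rose by 2.38 (SE 0.375) and RGA, a gibberellin-signalling repressor, by 0.44.

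Clock genes went both ways at the late time, while the light and starch lists were higher in CCA1-34. Of the 10 morning-phased clock genes (median 1.01, adjusted p = 0.0221, and adjusted p = 0.742 with an estimated correlation) CCA1 (6.12), PRR7 (2.56), LNK4 (2.30) and LNK3 (1.54) rose and RVE2 fell by 3.1, adjusted over the list alone. CCA1 is overexpressed by design in CCA1-34, so its rise and its part in this list's call were fixed in advance. The list was not tested without it. Among the evening-phased genes GI (2.64) and PRR3 (1.01) rose and ELF4 (-1.69) and JMJD5 (-1.52) fell, and the list did not pass (median -0.11, 0.866). The light regulators (median 0.12, 0.0192, and adjusted p = 0.742 with an estimated correlation) included CDF3 (2.48), BBX24 (2.45), CDF5 (2.02) and PHYB (0.63), and the starch genes (0.23, 0.000272, and adjusted p = 0.393 with an estimated correlation) the amylase AMY3 (1.23) and ISA3 (0.80). The lists for cell wall (0.30, 3.51e-07), gibberellin (0.24, 5.32e-05), ethylene (0.42, 0.000798), brassinosteroid (0.28, 0.00403) and abscisic acid and cold response (0.21, 0.00502) passed as well, with 2 gibberellin members and none of the others passing alone. For these 5 the adjusted p was 0.0973 to 0.507 with an estimated correlation. With the block XTH17 (0.97, adjusted p over the list alone 0.0146), XTH22 (1.00, 0.0370) and COB (0.44, 0.0401) of the cell wall list, GA3OX1 (1.23, 0.0114) of the gibberellin list, and DPE1 (0.62, 0.0413) and SEX4 (0.94, 0.0251) of the starch list passed too, and XTH22 also over the handling list (0.0286). Of the seed markers EM1 rose (1.81) and SESA1 fell by 1.36, and that list passed only with the block (median 0.67, adjusted p = 0.0378 against 0.122 without it). The list call is at the preset correlation, and without the block no list of this comparison passed at an estimated one (lowest camera adjusted p = 0.0973).

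In limma 2 probe sets passed at the late time, ACBP6 and ACS6, an ethylene biosynthesis gene (3.82 ± 0.03 in Col and 5.10 ± 0.08 in CCA1-34, SD, n = 3; difference 1.28, SE 0.133, adjusted p = 0.0180), with 861 at an unadjusted p under 0.05 against 1137.3 by chance, and 10.2% of probe sets without overlap where chance gives 10%. With the day as a block 6 passed, adding CCA1, AT1G73480 (2.08), AT2G41480 (1.54) and AT1G49230 (-1.97), each with adjusted p = 0.0360 and named after its values were seen. The ACS6 mean of Col late lay below the array medians and was not shown to be above background, so its difference is at best a lower bound. ACS6 lost its call without Col early replicate 2 (0.0578), without any Col late array (0.0548 to 0.149) or without any CCA1-34 late array (0.112 to 0.166). The count was 1 without each of those 7 arrays except Col late replicate 3, where it was 3, 4 without Col early replicate 1, CCA1-34 early replicate 2 or early replicate 3, and 12 without Col early replicate 3. Of the 49 member calls, in which a gene shared by lists counts in each, 33 held without any 1 array. Among the genes named above LNK3, GI, PRR3, ELF4, JMJD5, BEE1, IBH1, PIF6, IAA29, RGA, AMY3 and ISA3 lost theirs without at least 1 Col late or CCA1-34 late array (adjusted p over the list alone 0.0503 to 0.122). The morning-phased clock list missed the threshold without Col late replicate 2 (0.176) or CCA1-34 late replicate 3 (0.0523), brassinosteroid without Col late replicate 1 (median 0.17, 0.0553), and abscisic acid and cold response without Col late replicate 3 (0.11, 0.142) or CCA1-34 late replicate 1 (0.12, 0.0992). Without Col late replicate 2 the light regulators gave a median of 0.04 (0.396), the starch genes 0.16 (0.0779) and the cell wall list 0.48. Without CCA1-34 late replicate 3 the median was 0.01 for the light regulators and 0.17 for brassinosteroid. Without Col late replicate 1 it was 0.18 for the light regulators and 0.24 for ethylene, and without Col late replicate 3 it was 0.20 for the light regulators, 0.64 for ethylene and 0.39 for starch.

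Probe sets called growth-associated were those that differed in the same direction between each of the 3 growing groups and Col late. The data hold no measurement of growth, which is taken from the design text, and Col late is the only group without it. Growth can therefore not be told apart from time of day within Col, or from the line at the late time. This limit holds for PIF4 and PIF5 as for the other genes. The largest difference common to the 3 was that of RVE2, lower in the growing groups (-3.1 for the smallest of the 3 differences), and AT1G66100 was lower as well (-1.77). The largest among genes higher in all 3 were those of GI (2.64), PIF4 (2.52), CDF3 (2.48), BBX24 (2.45), PIF5 (2.30), LNK4 (2.30), COL5 (2.18) and PRR7 (2.17). Over the 9 arrays of the growing groups against the 3 Col late arrays, PIF4 was 2.79 higher and PIF5 2.42 higher (exact permutation test, two-sided, each p = 0.00455, the smallest that 220 assignments allow, Benjamini-Hochberg adjusted over 5 genes 0.0114), and CCA1 4.28 higher (0.0227, adjusted 0.0378). For CCA1 this says nothing of growth, since 6 of the 9 arrays are of the line that overexpresses it, and in Col alone early minus late was 1.08 (limma adjusted p = 0.909). LHY (-1.01, p = 0.3) and TOC1 (-0.66, p = 0.05, adjusted 0.0625) did not pass this exact permutation test, which was added after the data were examined.

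No probe set passed limma's adjusted threshold in all 3 contrasts, which passed 1, 3 and 2 probe sets, and with the block 1 did, AT1G73480. At an unadjusted p under 0.05 in all 3, 115 probe sets were higher and 62 lower in the growing groups. Simulated arrays of unchanged groups, whose 3 contrasts shared the simulated Col late arrays, gave 58.3 and 57.4 on average (at most 78 and 80 in 100 simulations). Independent lists would share 0.425 and 0.213. The simulated noise was independent between probe sets, so counts from arrays whose genes vary together may spread more widely. Sharing of the controls is thus in the simulated counts, but a deviation of the real Col late arrays common to many genes is not. These 3 arrays cannot be split into parts of at least 2, so part of the excess may still come from them. By list, the 115 held 4 morning-phased clock genes, 1 evening-phased clock gene, 3 bHLH factors, 3 shade- and PIF-induced, 4 auxin-induced, 3 cell wall, 1 gibberellin, 1 abscisic acid, 4 light-regulator and 4 starch genes, the 62 held RVE2, and the other lists contributed 0. The count was 1 without any 1 CCA1-34 early array and 2, PIF4 and PIF5, without Col late replicate 3.

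Seedling age differed between the replicates by 1 day each, and its slope was fitted with the group as a factor. Among the probe sets past the threshold, AT1G23130 (1.26 per day, SE 0.187, adjusted p = 0.0265), MAM1 of glucosinolate synthesis (1.13, 0.0302), AT1G67860 (0.94), AT3G61210 (0.93) and AT1G64370 (0.91) rose most steeply. AT2G47780 fell by 1.49 per day (SE 0.214, adjusted p = 0.0257), CASP5, a Casparian strip protein gene of the root endodermis, by 1.24 (0.0432), AT5G20790 by 1.19, SQP2, a squalene epoxidase gene, by 1.13 and AT5G44440 by 1.00. FLC, a repressor of flowering that was named after its values were seen, rose by 0.61 per day (SE 0.0572, adjusted p = 0.0138).

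Of 13 root cell markers, the control for the share of root tissue, 7 fell with age, adjusted over the list alone, with a list median of -0.32 per day (camera adjusted p = 1.1e-05, and adjusted p = 0.371 with an estimated correlation). In all 179 probe sets changed with age in limma, 123 upwards and 56 downwards, with 3743 at an unadjusted p under 0.05 against 1137.3 by chance. With the day as a factor, day 7 minus day 5, 102 passed, 90 of them among the 179, and AT1G67860, AT3G61210, CASP5, SQP2 and AT5G44440 no longer did (adjusted p 0.0528 to 0.0594). The count rested on single arrays: it was 0 without Col early replicate 1, 85 without Col early replicate 3, 427 without Col late replicate 2, 2 and 3 without CCA1-34 early replicate 1 and 3, and 1, 7 and 1 without CCA1-34 late replicate 1, 2 and 3.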

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

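The tests of ACBP6, of RNA quality and of handling genes and the counts over other splits of the arrays were chosen after the results were seen, while the tests of second lists of light- and dark-induced genes, and the age count without both early arrays that stand apart, were set before their results were seen.

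By camera's test of the interaction at its preset correlation, though not at an estimated one, the change from late to early differed between Col and CCA1-34 in 5 gene lists. The median interaction was 0.840 for PIF and growth-related bHLH factors, 1.15 for shade- and PIF-induced genes, 1.01 for auxin-induced genes, 0.332 for ethylene genes and 0.320 for starch genes. With an estimated correlation the adjusted p-values were 0.273, 0.358, 0.127, 0.562 and 0.545; fry passed 0 of them in one direction. The count of probe sets of the interaction was 0, which any regrouping reaches (100 of 100 drawn permutations of the times within each line), so that the comparison says nothing of chance; the highest gave 133. That regrouping set Col early replicates 2 and 3 and Col late replicate 2 against the other Col arrays, and CCA1-34 early replicates 1 and 2 and CCA1-34 late replicate 1 against the other CCA1-34 arrays. It was the highest of 100 draws, and whether it reflects a structure among the arrays other than the groups was not tested.

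Col early replicate 3 and CCA1-34 early replicate 2 stood apart in the direction that light before harvest would give. Against its group's other arrays, a second list of 8 light-induced genes lay at percentile 99.39 of 10000 random lists matched on mean expression in Col early replicate 3 (mean difference 0.62) and at percentile 100 in CCA1-34 early replicate 2 (1.02), and a second list of 11 dark-induced genes at percentiles 0.01 (-0.88) and 0 (-0.58). None of the 3 differences between 3' and 5' control probe sets was the highest of all arrays in either (0 of 3 and 0 of 3), which argues against degraded RNA. Handling and heat genes lay at percentile 65.4 in CCA1-34 early replicate 2. Its group's replicate 1 was itself high for this list (percentile 98.72), so the comparison cannot exclude handling there. In Col early replicate 3 the handling and heat genes lay at percentile 100, and light and handling both stay open. Random lists ignore co-regulation, and percentiles this extreme were common: 6 of 12 arrays lay outside the middle 95% for the light list and 9 of 12 for the dark list, 3 had the light list above and the dark list below it, the third being Col late replicate 1, and 2 had the handling list above it. Light or a shifted time of harvest may therefore be a candidate explanation but was not tested apart from a wrong label of time or day. ACBP6 stood at 3.74 in Col early replicate 3, where Col arrays held 3.44 to 3.85, and at 11.2 in CCA1-34 early replicate 2, where CCA1-34 arrays held 10.7 to 11.2. This argues against a swapped line in these 2 arrays. No biological explanation was tested, since the groups of the design give none.

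ACBP6 separated the lines by 6.87 between the lowest CCA1-34 array and the highest Col array. Of its 10 nearest measured genes 4 had a CCA1-34 mean above the array medians, ABCG14, CYP97A3, NFD3 and PUT2, and 0 of these were lower in Col by 1 or more at both times (largest absolute difference 0.317), which argues against a lost or silenced stretch of chromosome that reaches them, while the other 6 were too dim to test a shorter one. Between the Col arrays with the highest and the lowest CCA1 value, 6.37 and 2.47, ACBP6 differed by 0.0200, but at a level below the array medians this excludes no link to the CCA1 transcript. A difference between the seed stocks at this gene and an effect of the CCA1 transgene or its insertion cannot be told apart, because each line is a single stock. For the late comparison as a whole 1 of the 10 splits of the 6 arrays gave as many probe sets as the real 2 (highest other 1), and for the early comparison 1 of 10 gave as many as the real 1 (highest other 0), and 10 splits are too few for a share under 0.05.

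The 179 probe sets that changed with seedling age exceeded the other regroupings. Of 100 permutations of the ages within groups 1, the real one, gave as many, and the highest other gave 9. Noise independent between the groups can thus be excluded at a share of 0.05. The permutations also parted arrays of the same day, and each age was sampled on 1 day. They therefore cannot tell a slope with age from chance differences between the days. Of the 3 differences between 3' and 5' control probe sets 0 changed with age by more than 2 standard errors, but that of GAPDH rose by 1.84 standard errors, so that a drift of RNA quality stays open. Without both early arrays that stand apart 213 probe sets passed, which argues against those arrays as the source of so many calls, but 83 of the 179 were among them, so that which probe sets passed did depend on these arrays. Root cell markers fell with age as well (7 of 13 over the list alone, list median -0.32 per day, adjusted p = 0.371 with an estimated correlation), so that a smaller share of root tissue on later days stays open. Since all seedlings had 4 short days first, older ones may also have spent longer under the light pulses. Differences in development, in time under the light pulses and between the 3 days of sampling cannot be separated by the design, and none was tested.

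For Col early minus late 3 of the 10 splits of the 6 arrays gave as many probe sets as the real 1 (highest other 1), and for CCA1-34 early minus late 10 of 10 gave as many as the real 0 (highest other 0), and 10 splits are too few for a share under 0.05. For the growth-associated probe sets, 0 in the real groups, 100 of 100 drawn groupings gave as many, as any must, and the highest gave 12, which says nothing of chance. Among the splits that put 1 array of each day on each side, as the real one does, the highest other was 0 in each of the 4 comparisons of groups. Single outlying values within groups were not tested by their gap to the nearest value, because groups of 3 are too small for it.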

How the results depend on the processing

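Leaving out both early arrays that stand apart was chosen after the results were seen, and the other alternatives were set before. For Col early minus late (1 probe set) array weights gave 20, the arrays of age 5, 6 or 7 days left out gave 0, 0 and 2, both early arrays left out gave 13, and single arrays left out gave 0 to 3. For CCA1-34 early minus late (0) single arrays left out gave 0 to 1. For the interaction (0) the arrays of age 7 days left out gave 1 and both early arrays left out 1, SAUR9. For the lines at the early time (1) an intensity trend with robust prior, median centring, quantile normalization and dim probe sets left out each gave 2, and single arrays left out 1 to 3. For the lines at the late time (2) the replicate block gave 6, the trend 6, dim probe sets left out 5, array weights 120, age 6 days left out 1, age 7 days left out 7, both early arrays left out 30, the 2 groups alone 22 and single arrays left out 1 to 12. For growth-associated probe sets (0) the block, the trend and dim probe sets left out each gave 1, array weights 8, age 7 days left out 2, both early arrays left out 9 and single arrays left out 0 to 2. For seedling age (179) the block gave 102, the trend 110, dim probe sets left out 95, the minimum change 65, array weights 1151, each age left out 0, both early arrays left out 213 and single arrays left out 0 to 427. The CCA1 difference passed at the late time with the block, the trend, dim probe sets left out, the 2 groups alone and both early arrays left out (6.12 each) and with array weights (5.72), with 5.73 to 6.37 without single arrays, and at the early time it was 3.62 to 5.57. Of the 95 list tests 33 passed, against 0 with an estimated correlation, 0 with fry, 13 with fry's mixed test, 37 with the block, 27 without both early arrays and 27 to 38 without single arrays. The light regulators in CCA1-34 early minus late reversed, with a median of -0.04 (-0.0389) without CCA1-34 early replicate 2 and without both early arrays, in a range of -0.04 to 0.68 without single arrays. Of 77 member calls 74 passed with the block, 72 without both early arrays and 51 to 75 without single arrays, and 0 reversed.

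Fewer arrays by themselves lower the power of a test. Yet counts also rose in some settings with arrays left out, and why was not tested. They went from 2 to 30 for the lines at the late time without both early arrays, and from 179 to 427 for seedling age without Col late replicate 2. The fit without dim probe sets tests fewer of them, and for the other settings the cause was not tested. The block added 17 member calls and ended 3. These and its changes to counts, list calls and age genes stand beside the results, apart from HAT3 at the late time (adjusted p over the list alone 0.0642), and it changed no other call. The table of the whole series held identical values and gave no alternative. No background measurement per probe was analysed here, so what signal over background limits was judged only by leaving out dim probe sets.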

Other observations

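The list tests of the age slope and the comparison of all arrays of the lines were chosen after the results were seen.

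Of 13 root cell markers 7 fell with seedling age between 5 and 7 days, adjusted over the list alone (0 over all probe sets), among them the root hair genes COBL9 (-0.44 per day, SE 0.118), EXPA7 (-0.60) and PRP3 (-0.66), the epidermal regulator WER (-0.37) and the auxin transporter gene PIN2 (-0.25), and the list had a median slope of -0.32 (camera adjusted p = 1.1e-05, and adjusted p = 0.371 with an estimated correlation). ICL and MLS, the glyoxylate cycle enzymes with which seedlings use stored oil, fell by 1.39 and 1.1 per day over the seed list alone, while the seed list as a whole did not pass (adjusted p = 0.621). Of 20 genes of abscisic acid and cold response 5 fell, among them RD29A (-0.56) and RD29B (-0.57), and COR15A rose by 1.56 (list 0.00106, and adjusted p = 0.328 with an estimated correlation). The evening-phased clock list had a median slope of 0.28 (0.00298, and adjusted p = 0.371 with an estimated correlation), and of its 10 genes LUX (0.35) and TOC1 (0.31) rose, adjusted over the list alone. The flavonoid synthesis list, of which F3PH (-0.71) fell over the list alone, had a median of -0.35 (0.0115, and adjusted p = 0.883 with an estimated correlation). It missed the threshold without Col late replicate 1 (median -0.22, 0.0757), Col late replicate 3 (-0.31, 0.0647) or CCA1-34 early replicate 3 (-0.12, 0.124). Without Col early replicate 3 its median was larger, at -0.72. The other 3 lists passed without any 1 array. Their medians moved, to -0.20 for the root cell markers without Col late replicate 3 and to -0.09 for abscisic acid and cold response without CCA1-34 early replicate 1. The other 15 lists did not pass in the full data, although the gibberellin biosynthesis gene GA3OX1 (-0.77, adjusted p over all probe sets 0.0265), the cell wall gene XTH33 (-0.88, 0.0397) and the auxin-response gene IAA14 (0.51, 0.0265) passed singly.

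All 6 arrays of CCA1-34 lay on 1 side of all 6 Col arrays for 87 probe sets, where chance gives 49.2, and 18 of these had 1 gene and a difference of at least 1. Besides ACBP6 and CCA1, examples picked after their values were seen are HFR1 (2.23), EM1 (1.78), the cytokinin oxidase gene CKX5 (1.55), ECP63 (1.28) and LEA (1.28), higher in CCA1-34. AT3G25150 (-2.26), AT1G49230 (-1.64) and PSKR2, a peptide receptor gene (-1.31), were lower in CCA1-34. Apart from ACBP6 none of the 18 passed in the main limma fit at either time (lowest adjusted p 0.0544 early and 0.0588 late). With the day as a block CCA1, AT1G49230 and AT2G41480 passed at the late time (limma adjusted p = 0.0360 each). Over 24 alternatives, the 2 groups fitted alone and single arrays left out included, CCA1 passed in 8 at the late time (adjusted p 0.00135 to 1) and 1 at the early time (0.0185 to 1). AT3G25150 passed in 7 late (0.00388 to 1.00) and 6 early (0.00203 to 1), and AT1G49230 in 7 late (0.00380 to 1) and 0 early (0.388 to 1). The other genes passed in at most 2 at the late time and in 0 at the early time.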
